A study of Mus musculus with 4 samples.

How the data were processed

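Single-cell RNA-seq was analysed from 4 mouse libraries, 1 per treatment group, made per the labels from lymph node with a droplet kit that reads the 3' ends of polyadenylated transcripts. The groups were a control (ctrl), 2-deoxy-D-glucose (2DG, a glucose analogue), aPDL1, and both treatments together (2DG_aPDL1, called the combination here). The deposited values were raw UMI counts per gene and cell barcode, whole numbers with no normalization, per the file headers. Cell Ranger 7.0.0 is named in the matrix headers, while Cell Ranger 3.1.0 and the mouse build mm10 are named in the submitters' processing notes. Which version made the counts could not be settled, and whether intronic reads were counted is not given in the sources used here. Gene symbols and identifiers were taken as the files pair them, for 32285 genes.

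The matrices held 9655 barcodes for ctrl, 8701 for 2DG, 9764 for aPDL1 and 9948 for the combination. Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which left 9091, 7943, 9044 and 9294 cells in that order. Doublets were scored per library with Scrublet as built into scanpy 1.11.5, and the highest-scoring cells were removed at 0.8% per 1000 barcodes, which took out 702, 553, 706 and 740 cells. The automatic threshold of the same tool marked 0% of the ctrl barcodes and 2.29%, 2.80% and 3.28% of the others, so it was not used. The cells analysed numbered 8389 for ctrl, 7390 for 2DG, 8338 for aPDL1 and 8554 for the combination.

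Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes without immunoglobulin and T cell receptor segment genes gave 30 principal components, 15 neighbours and 29 Leiden clusters at resolution 1. No batch integration was used, since library and treatment are the same thing in this design. Clusters were named from marker genes of 21 classes and states, and every class name below means cells like that type by these markers. Each marker was scaled from its lowest to its highest cluster, and the class with the highest mean score of at least 0.4 gave the name. CD4 and CD8 T cells were parted by a 4-fold difference between Cd4 and the Cd8 genes, and a cluster between them was called T of both kinds.

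The naming rule was changed after the names had been seen. 6 versions were looked at, which ranked the 10 leading genes of a cluster with 1, 10 or 100 CPM added, and did or did not restrict names to classes with 3 detected markers. With 1 CPM, cluster 3 was unnamed in both versions, because the Plasma marker Sdc1 was among its leading genes with no marker of its own class, and cluster 6 was unnamed without the restriction. With 10 CPM, clusters 8 and 28 were unnamed, and cluster 6 as well without the restriction. With 100 CPM, cluster 6 alone was unnamed without the restriction. The version used, 100 CPM with the restriction, was the only one that named every cluster, so results that hang on cluster 3, cluster 8, or clusters 3 and 6 together are given without them as well. The fibroblastic stroma class is cluster 28 alone and ends in the versions with 10 CPM. There an epithelial or tumour marker was among the leading genes of the cluster, with no marker of its own class.

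Raw UMIs were summed per library and class, and CPM were taken over the UMIs of the class. The 2DG comparison used 2 pairs, 2DG over ctrl and the combination over aPDL1. The aPDL1 comparison used aPDL1 over ctrl and the combination over 2DG. Both comparisons draw on the same 4 libraries and are not independent. A gene or list lowest in ctrl and highest in the combination, or the reverse, can pass both. The combination was also set against the other 3 libraries. Log2 ratios used counts plus 0.5. With 1 library per group nothing measures the spread within a group, so no test was made, no p-value is given, and no difference has a replicate check. Shares carry exact Clopper-Pearson 95% intervals and CPM carry exact Poisson 95% intervals, which cover counting error only.

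Genes were named by a rule of size. In each main class, up to 5 genes per direction were taken that moved the same way by at least 1.5-fold in both pairs, with at least 50 UMIs in the higher library of each pair, ranked by the smaller ratio. For the combination, up to 5 genes per direction lay at least 1.5-fold outside the range of the other 3 libraries. Receptor segment, haemoglobin and mitochondrially encoded genes were left out of the ranking, and 24 genes were to be reported always. A few of the genes these rules named are not reported here. Main classes were to hold at least 200 cells in every library, which 2 classes did. The CD8 T class held 144 ctrl cells and was added after its values were seen. The number of genes past the size rule was set beside the number that moved in opposite directions in the 2DG pairs, which holds any effect of 2DG that differs with aPDL1 and is no baseline.

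For 21 gene lists, the median log2 ratio over genes with at least 40 UMIs was placed among 10000 random lists of the same size matched on expression in 20 bins. Its percentile describes these libraries only, and a list is said to stand apart when it lay below percentile 2.5 or above 97.5 in both pairs with the same sign. The size rule was tested on simulated data for the 2DG comparison with 200 genes changed. The changed genes, 50 per fold, were drawn from 10933 genes in the monocyte or macrophage class, 2450 in neutrophils and 3711 in CD8 T cells. Of those changed 2-fold, the rule passed 100%, 98% and 96% in that order, and of those changed 1.25-fold 0%, 4% and 0%. Of 11817, 8374 and 9369 unchanged genes with at least 50 UMIs in the higher library of the first pair, 1, 0 and 4 passed. The simulated counts were Poisson draws around 1 pooled profile per class, so they held counting error and no spread between libraries. The changed genes had at least 50 expected UMIs in every library, which the size rule does not ask. These pass rates therefore do not show how often single libraries differ without treatment.

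The groups, filters, markers, gene lists, size rule and the other settings listed here were fixed before the data were examined. Those settings changed the cell filter, doublet removal, clustering resolution, scaling, thinning, pseudocount, list filter and size rule, and edgeR 4.0.16 gave TMM factors for one of them. Leaving clusters 3, 6 or 8 unnamed and using the pair without ctrl alone were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 were used. The series design text mentions young and aged mice, but no label gives an age, so age was not analysed here.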

Results

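Cells of 4 mouse libraries were profiled in a study of glycan targeting and immune checkpoint blockade in ovarian tumours, with 1 library each for ctrl, 2DG, aPDL1 and their combination. The libraries held 73885214 UMIs for ctrl, 61859753 for 2DG, 62823127 for aPDL1 and 65369018 for the combination. Median UMIs per barcode were 5632, 6243, 5861.5 and 6000.5 in that order, and median detected genes were 1901, 2346, 2268 and 2260.5. No group had replicates, so every comparison is between single libraries.

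The ctrl library differed from the other 3 in its cell classes. T and NK cells together made up 6.52% of ctrl cells (95% interval 6.0 to 7.07), against 45.7% with 2DG (44.6 to 46.9), 40.1% with aPDL1 (39.0 to 41.1) and 39.4% in the combination (38.4 to 40.5). CD8 T cells made up 1.72% of ctrl cells (1.45 to 2.02), 20.5% with 2DG (19.6 to 21.4), 19.6% with aPDL1 (18.8 to 20.5) and 18.7% in the combination (17.9 to 19.5). Neutrophils went the other way, with 35.8% in ctrl (34.7 to 36.8) against 4.36% (3.90 to 4.85), 3.23% (2.86 to 3.63) and 3.45% (3.07 to 3.86). NK cells were at 0.441% in ctrl (0.311 to 0.607) and 4.36%, 4.11% and 5.34% in the others. Regulatory T cells were at 1.79% in ctrl, 7.92% with 2DG, 4.68% with aPDL1 and 3.74% in the combination. No cell was left unnamed, but that rests on the naming rule chosen after the names had been seen.

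Monocytes or macrophages gave no direction that held both with and without cluster 3. Under the naming rule used they made up 51.0% of ctrl cells (49.9 to 52.1), 39.9% with 2DG (38.8 to 41.0), 46.3% with aPDL1 (45.3 to 47.4) and 45.7% in the combination (44.6 to 46.8). Without cluster 3, which other versions of the rule left unnamed, they made up 30.4% (29.4 to 31.4), 38.6% (37.5 to 39.8), 42.7% (41.6 to 43.7) and 44.6% (43.5 to 45.6), and the order against ctrl was turned. Cluster 3 held 1728 ctrl cells and 94, 306 and 96 cells of the others, and a cluster mostly of 1 library may be that library rather than a type. Its score was 0.728 for monocytes or macrophages, with 9 markers of that class detected, and 0.565 for type 2 dendritic cells, the next class. None of its leading genes was a marker of the class. By score its cells lay nearest to this class, so the shares without it may leave out cells of the class. The largest clusters of the class differed, with clusters 3 (40.4%) and 2 (23.2%) in ctrl, 21 (21.7%) and 17 (20.1%) with 2DG, 17 (22.1%) and 9 (18.6%) with aPDL1, and 21 (32.7%) and 9 (18.7%) in the combination. Neutrophils lay most often in cluster 1 in ctrl (79.2%) and in cluster 6 in the other libraries (69.9%, 49.1% and 61.0%). CD8 T cells lay most often in cluster 0 in ctrl and 2DG and in cluster 22 in aPDL1 and the combination.

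**Figure D1:**
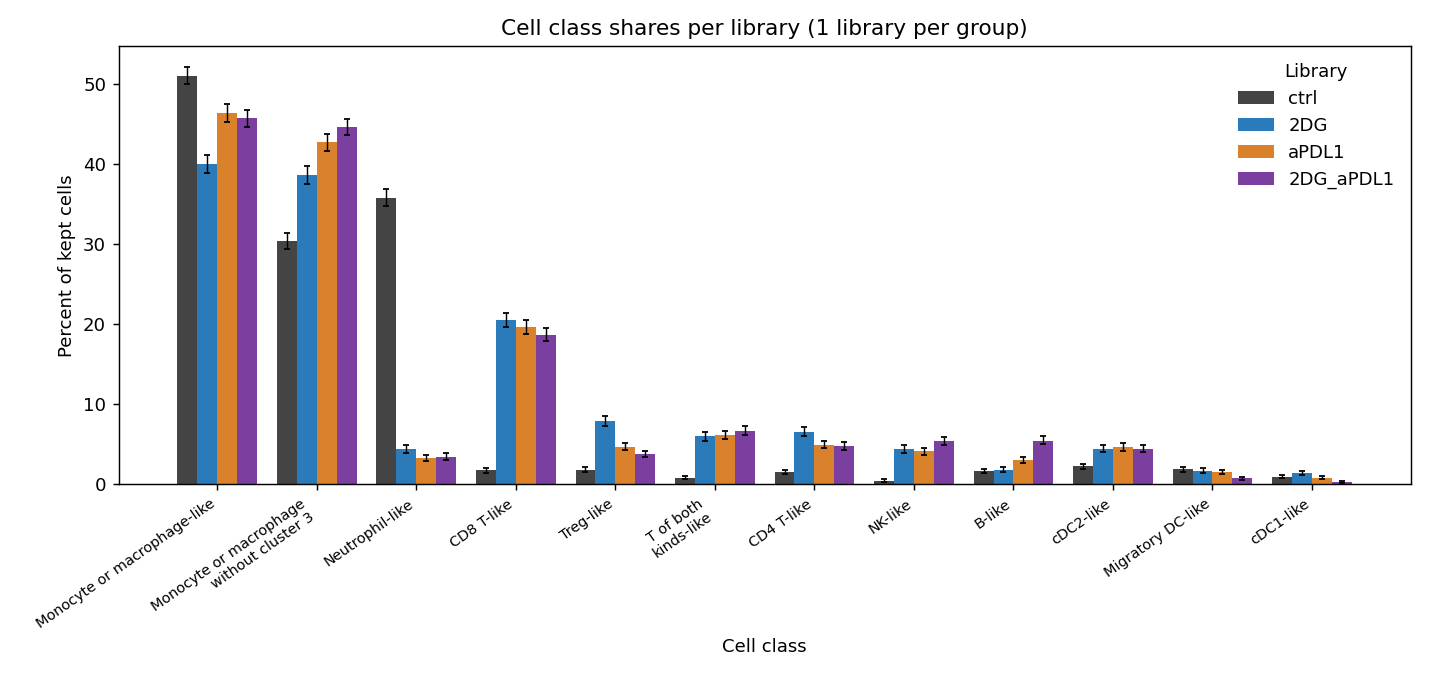
Percent of kept cells (vertical axis) in each cell class for the 4 libraries, with bars for the shares and lines for exact 95% Clopper-Pearson intervals, which cover counting error only. CD8 T cells stood at 1.72% in ctrl and at 18.7% to 20.5% in the other libraries, neutrophils at 35.8% and at 3.23% to 4.36%, and the monocyte or macrophage order against ctrl turned when cluster 3 was left out (30.4% in ctrl).

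The 2DG comparison asked what a glucose analogue, which interferes with glycolysis and with protein glycosylation, went with when given alone and when added to aPDL1. In monocytes or macrophages, genes of the interferon gamma response were higher in both pairs, with a median log2 ratio of 1.13 without aPDL1 and 0.45 with it, and 21 and 20 of 21 genes higher. Within clusters 7, 8, 9, 16 and 17 the medians with aPDL1 were -0.04, 0.09, 0.35, 0.40 and 0.14, against 0.45 for the class. MHC class I genes, which present peptides to CD8 T cells, had medians of 0.68 and 0.47, with H2-K1 at 698, 1216, 1241 and 1482 CPM. Type I interferon response genes had medians of 0.67 and 0.36, with 28 and 27 of 31 genes higher. All 3 lists lay at percentile 100 in both pairs and stayed there without cluster 3, where the interferon gamma medians were 0.86 and 0.44.

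Glycolysis genes were lower with 2DG in monocytes or macrophages under the naming rule used, with medians of -0.45 and -0.30 and 17 and 20 of 22 genes lower. Slc2a1, the glucose transporter GLUT1, was at 485 CPM in ctrl (479 to 492), 217 with 2DG (211 to 223), 252 with aPDL1 (246 to 258) and 195 in the combination (190 to 201). Without cluster 3 the list no longer stood apart, at medians of -0.11 (percentile 6.56) and -0.20 (percentile 0.65), and Slc2a1 was at 232, 189, 196 and 180 CPM. Heat shock genes stood apart as lower, with medians of -0.34 and -0.31 (-0.64 as a mean for the second), and so did cell cycle genes at -0.30 and -0.42, although the first cell cycle median was 0.03 with no doublet removal and -0.84 without cluster 3. Cluster 18, led by proliferation genes, made up 3.67% of the class in ctrl and 0.136%, 0.0518% and 0.0256% in the other libraries. The N-glycosylation list stayed within the random range in every class and pair, and its 39 genes had medians of 0.06 and -0.13 here. It holds genes that join glycans to proteins in the endoplasmic reticulum and genes of other steps, such as Mgat5. Its median is therefore no readout of a single step.

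Among the 10 genes the size rule named in this class, Ccl8, a monocyte-attracting chemokine, was at 44.5 CPM in ctrl (42.5 to 46.6), 305 with 2DG (298 to 312), 128 with aPDL1 (124 to 132) and 423 in the combination (415 to 430). Ccl8 also leads clusters 4, 7 and 21, and its level within single clusters was not computed. Ankdd1a was higher by log2 2.49 and 2.07, at 0.741, 4.21, 2.73 and 11.5 CPM, and Heatr9 and Gm14009 by 4.60 and 1.98 and by 3.12 and 1.97. Atp6v0d2, a subunit of the vacuolar proton pump, was lower, at 16.2 CPM in ctrl (15 to 17.5), 3.17 with 2DG (2.5 to 3.97), 5.72 with aPDL1 (4.86 to 6.68) and 0.831 in the combination (0.532 to 1.24). Its ratio with aPDL1 was -2.76, and -1.43 with no doublet removal. Zfp532 was lower by log2 -2.31 and -2.14, but by -1.29 in the first pair without cluster 3. Car4, a carbonic anhydrase, was lower by -2.17 and -2.24, but by -0.56 in the first pair without cluster 3. Retnlg and Mmp9, also named as lower, are neutrophil genes that reached 121 and 71.4 times the class level in neutrophils, and Prg4, named as higher, reversed to -3.26 with aPDL1 when 2 times the doublet rate was removed.

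In neutrophils, interferon gamma response genes were higher with 2DG in both pairs, at medians of 1.88 and 0.55 with 20 and 18 of 21 genes higher, and at 1.03 and 0.32 when clusters 3 and 6 were unnamed. MHC class II genes, abundant in other cell types, had medians of 1.19 and -0.20 in the same pairs, and free RNA from other cells was not tested in this class. MHC class I genes had medians of 1.23 and 0.38 (0.21 with TMM factors) and ribosomal protein genes 0.41 and 0.52 (0.20 for the first with TMM factors). Cell cycle genes had medians of 2.08 and 0.82, which came to 0.72 and 0.09 when 2 times the doublet rate was removed. That setting took cluster 25 from 28 to 0 cells with 2DG but from 70 to 66 in ctrl, and this cluster made up 2.33% of the class in ctrl, 8.70% with 2DG, 13.4% with aPDL1 and 4.75% in the combination. The list was not computed without this cluster. Soga1 was at 4.17 CPM in ctrl (3.21 to 5.33), 46.9 with 2DG (35.1 to 61.3), 11.2 with aPDL1 (5.38 to 20.6) and 63.9 in the combination (48.4 to 82.8), while monocytes or macrophages held 17.4 to 88.3 CPM. Nfkbie, an inhibitor of NF-kB, was higher by log2 1.38 and 1.48 (0.98 for the second when clusters 3 and 6 were unnamed), and Jmy and Rab3gap2 were lower by -1.77 and -1.49 and by -1.20 and -1.20 (-0.71 for the first of Rab3gap2 when clusters 3 and 6 were unnamed). Hist1h2ap, Hist1h1b and Gm40578, named as higher, and Hsph1, named as lower, each reversed in at least 1 pair under another setting, and the heat shock genes Hspa1a and Hspa1b, also named as lower, were lowest in the combination in all 9 classes examined.

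In CD8 T cells, glycolysis genes were lower with 2DG, with medians of -0.27 and -0.38 and 17 and 21 of 22 genes lower. The first median was -0.03 at Leiden resolution 0.5 and 0.10 at resolution 2, so its direction turned with the clustering. Gzmf, a granzyme, had 0 UMIs among 1047774 in ctrl and was at 33.4 CPM with 2DG (30 to 37), at least 11.6-fold over a floor of 3 UMIs, or 2.86 CPM. It was at 8.42 CPM with aPDL1 (6.75 to 10.4) and 29.3 in the combination (26.1 to 32.7). The metallothionein gene Mt1 was lower, at 119 CPM in ctrl (99.3 to 142), 33.1 with 2DG (29.7 to 36.7), 124 with aPDL1 (117 to 131) and 49.3 in the combination (45.2 to 53.7), and Mt2 followed at 21, 8.62, 34.2 and 8.86 CPM. With no doublet removal the Mt1 ratios of -1.85 and -1.33 came to -1.09 and -0.71, at Leiden resolution 2 the first Mt2 ratio came to -0.34, and monocytes or macrophages held 859 to 2698 CPM of Mt1. Plat, the tissue plasminogen activator, had 3 ctrl UMIs and log2 ratios of 1.72 (0.36 to 4.24) and 1.68 (1.34 to 2.04), the first at 0.52 with no doublet removal and 4.54 at Leiden resolution 2. Klra7, with 2 ctrl UMIs, reversed at both other resolutions, Gm15345 and Gm13571 rested on 1 and 2 ctrl UMIs, and Unc13b was lower by -1.34 (-0.20 at Leiden resolution 2) and -1.43. Slc15a2 and Bnip3, also lower, lay below their levels in monocytes or macrophages, and reads of related granzyme and Klra genes can be hard to tell apart.

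The aPDL1 comparison asked what the treatment labelled aPDL1 went with alone and on top of 2DG. It used the same 4 libraries as the 2DG comparison, so a list that stood apart in both gives no separate evidence for each treatment. In monocytes or macrophages these were the interferon gamma, type I interferon, MHC class I, heat shock, cell cycle and glycolysis lists. Interferon gamma response genes in this class were higher by medians of 1.35 and 0.43, with 21 of 21 genes higher in both pairs. Within clusters 7, 8, 9, 16 and 17 the medians on top of 2DG were 0.08, 0.04, 0.48, 0.35 and 0.42. Type I interferon response genes followed at 1.0 and 0.57 with 31 and 30 of 31 genes higher, and MHC class I genes at 0.50 (0.32 without cluster 3) and 0.40. NF-kB target genes were higher by 0.49 (0.32 without cluster 3) and 0.60. Cell cycle genes were lower by -0.63 (-1.18 without cluster 3 and -0.39 with no doublet removal) and -0.65, where cluster 18 again lay almost only in ctrl, and heat shock genes by -0.37 and -0.33 (-0.70 as a mean for the second). Lower Myc and ribosome biogenesis genes, at -0.10 and -0.26, ranged from -0.30 without cluster 3 to -0.03 without cluster 8 in the first pair. Glycolysis genes, at -0.33 and -0.14, came to -0.04 and -0.12 without cluster 3, and B cell activation genes, at 0.50 and 0.13, came to 0.21 (percentile 96.0) and 0.15, so neither list stood apart in both pairs then.

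Named by the size rule in the same class, Hspb1, a small heat shock protein, was lower with aPDL1, at 18.7 CPM in ctrl (17.4 to 20.1), 4.42 with 2DG (3.62 to 5.34), 1.97 with aPDL1 (1.48 to 2.57) and 0.658 in the combination (0.396 to 1.03). Car4 was lower by log2 -3.14 (-1.12 without cluster 3) and -3.21, and Retnlg, Hist1h3c and Fam13a by -2.53 and -3.05, -3.11 and -2.10, and -3.01 and -1.70. Retnlg is a neutrophil gene, and Hist1h3c led cluster 18, of which 95.7% came from ctrl. Cd209a, a C-type lectin that was also a dendritic cell marker here, was higher by 2.31 (1.20 at Leiden resolution 2) and 2.06. Tgfb2, Alox15, Prg4 and Cd5l, also named as higher, each reversed against 2DG when 2 times the doublet rate was removed, which cut cluster 14 to between 6 and 34 cells per library. Pdcd1lg2, the gene of PD-L2, was at 16.7 CPM in ctrl and 85.0, 81.6 and 86.3 CPM in the others, and Cd274, the gene of PD-L1, at 413 CPM (407 to 420), 500 (491 to 509), 479 (471 to 488) and 630 (621 to 639).

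In neutrophils, aPDL1 went with higher MHC class I genes at medians of 1.16 and 0.32 (0.20 with TMM factors for the second), type I interferon response genes at 0.71 (0.37 with at least 1000 genes) and 0.26 (0.14 with TMM factors), and NF-kB target genes at 0.53 (0.23 with at least 1000 genes) and 0.40. The ribosomal protein medians of 0.31 and 0.43 became 0.15 and -0.12 with no doublet removal, and those of 8 cytotoxic and effector genes, 1.01 and 0.89, became 0.43 and 0.36 with 2 times the doublet rate removed. The cytotoxic and effector list holds genes that lead a CD8 T cluster, and T and NK cells were fewest in ctrl. Doublets with those cells and free RNA from them were not tested as a source of these medians. Wfdc17 was lower, at 3731 CPM in ctrl (3700 to 3761), 1051 with 2DG (992 to 1113), 980 with aPDL1 (916 to 1047) and 498 in the combination (453 to 546), and its second ratio of -1.08 became -2.09 when clusters 3 and 6 were unnamed. Csta2, of the cystatin family of protease inhibitors, was lower by log2 -1.25 (-0.81 when clusters 3 and 6 were unnamed) and -1.49, and Swt1 by -1.02 and -0.86. Slc8a1, Rasgef1b, H2-Aa and S100a4, named as higher, lay below their levels in monocytes or macrophages in every library, with H2-Aa at 62.8 against 2172 CPM with aPDL1, and H2-Aa reversed with no doublet removal. Hist1h1b and Ppp1r16b reversed in at least 1 pair under another setting.

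In CD8 T cells, cytotoxic and effector genes were higher with aPDL1, with medians of 0.28 and 0.46 (0.29 as a mean for the second) and 16 and 17 of 21 genes higher. S100a4 was at 800 CPM in ctrl, 1061 with 2DG, 1469 with aPDL1 and 1562 in the combination, while Ccl5, Nkg7, Ifng and Prf1 of this list also lead cluster 22, which held more of the class in the aPDL1 libraries. Nuclear oxidative phosphorylation genes were higher by 0.17 and 0.18, in 34 and 41 of 41 genes. Heat shock genes were lower by -0.64 and -0.26 (-1.06 as a mean for the second), though Hspa1a and Hspa1b of this list were highest in ctrl and lowest in the combination in all 9 classes examined, and cell cycle genes by -0.55 (-0.30 at Leiden resolution 0.5) and -0.22 (-0.13 at Leiden resolution 0.5). Myo10, an unconventional myosin, was at 88.8 CPM in ctrl (71.6 to 109), 122 with 2DG (115 to 129), 316 with aPDL1 (305 to 327) and 376 in the combination (365 to 388). Slc17a6, a vesicular glutamate transporter, was at 22 CPM (13.9 to 32.9), 48.7 (44.6 to 53.1), 92.5 (86.8 to 98.5) and 140 (133 to 147). Klrc3, an NK receptor gene, had 0 ctrl UMIs and was at least 2.91-fold higher with aPDL1, and Gm15638 at least 1.67-fold. Fam20a was higher by log2 2.49 and 1.47, and Kcnip3 was lower by -1.99 and -1.80. Cd4 was lower by -1.64 and -1.70 and is a marker used to part the T cells, and Plcb4, also lower, reversed at both other resolutions. Pdcd1, which encodes PD-1, was at 207 CPM in ctrl (180 to 237), 195 with 2DG (187 to 204), 281 with aPDL1 (271 to 292) and 263 in the combination (253 to 273).

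**Figure D2:**
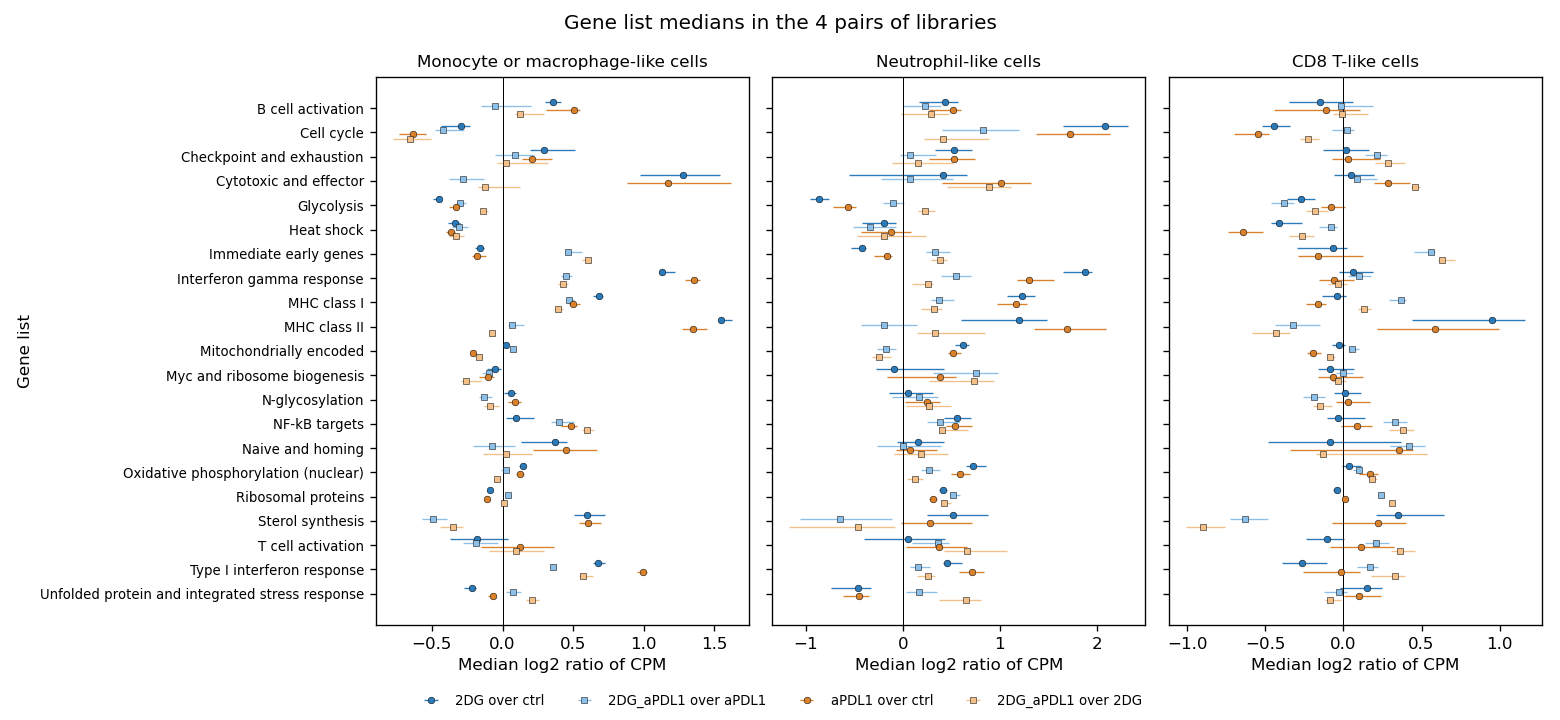
Median log2 ratio of CPM (horizontal axis, with different ranges in the 3 panels) of 21 gene lists in monocytes or macrophages, neutrophils and CD8 T cells for the 4 pairs, with lines for 95% intervals from redrawn Poisson counts. Interferon gamma response genes in monocytes or macrophages were at 1.13 and 1.35 against ctrl and at 0.45 and 0.43 in the pairs without ctrl, glycolysis in CD8 T cells was at -0.27 against ctrl but 0.10 at Leiden resolution 2, and sterol synthesis genes in monocytes or macrophages went from 0.60 to -0.49 between the 2DG pairs.

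In the combination, B cells made up 5.45% of cells (4.98 to 5.95), against 1.62% in ctrl (1.36 to 1.91, and 1.30% without cluster 24), 1.77% with 2DG (1.48 to 2.10) and 2.97% with aPDL1 (2.62 to 3.36). Conventional type 1 dendritic cells were at 0.234% (0.143 to 0.361), against 0.930%, 1.35% and 0.756%, and migratory dendritic cells at 0.736% (0.566 to 0.941), against 1.84%, 1.64% and 1.54%. In monocytes or macrophages, Cxcl13, a chemokine that attracts B cells, was at 13.3 CPM in the combination (12 to 14.7) and at 0.250 with 2DG and 1.38 with aPDL1 (0.979 to 1.90). It had 0 UMIs in ctrl, so the combination was at least 185-fold over a ctrl floor of 3 UMIs, or 0.0717 CPM. Ccl17, a chemokine that led the type 2 dendritic cell cluster, was at 0.831 CPM (0.532 to 1.24) against 23.5, 17.4 and 32.1 CPM, and its ratio to the nearest library of -4.36 became -2.73 with 2 times the doublet rate removed. Gm17080 was at 3.60 CPM against 0.0717 to 0.667 CPM. Vmn2r26, Timd4 and Ltbp1, named as higher, reversed with 2 times the doublet rate removed, and Lyve1, with 1 UMI in the combination, reversed with no doublet removal. Retnlg, Wdr95 and Hspa1b, named as lower, were as high or higher in other classes.

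In CD8 T cells of the combination, Abcb1b, a drug efflux pump, was at 343 CPM (332 to 354), against 89.7 in ctrl (72.5 to 110), 71.8 with 2DG (66.8 to 77.1) and 87.9 with aPDL1 (82.3 to 93.8). Gm26532 was at 89.7 CPM against 18.4 to 22.1, Morn3 at 15.6 against 0 to 3.13, Gm15638 at 22.7 against 0 to 4.78, and Dbn1 at 6.53 against 0 to 1.71 CPM. The granzyme gene Gzmg had 1 UMI in the combination, with a log2 ratio of -6.34 (-12.23 to -4.41) to aPDL1 and -6.92 (-12.81 to -5.00) to 2DG, while Gzme and Nckap5 reversed at other resolutions. Hspa1a and Hspa1b were at 7.46 and 12.4 CPM, against 54.9 to 255 and 76.4 to 387 CPM. Ctla4, which encodes an inhibitory receptor, was at 938 CPM (920 to 957), against 697 (647 to 749), 503 (490 to 517) and 540 (526 to 554), and Gzmb, which encodes granzyme B, at 727 (711 to 744), against 447 (407 to 489), 391 (379 to 403) and 544 (530 to 558). Cluster 22, led by effector genes such as Prf1, held 52.1% of the class in the combination. It held 26.4% in ctrl, 33.9% with 2DG and 45.5% with aPDL1, and the levels of both genes within single clusters were not computed.

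In neutrophils of the combination, Zc3h12c was at 47.1 CPM (33.9 to 63.7) against 3.52 to 6.19 CPM, with a ratio to the nearest library of 2.84 that became 1.23 with 2 times the doublet rate removed. Ncapd3 was at 38.1 CPM against 4.83 to 7.08, and Mef2c, at 54.9 CPM, lay below its level in monocytes or macrophages. Ccr9 reversed under another setting. Gm50240, Gm26982, Sptb, Ggt1 and Sdc3 had 0 UMIs among 891739 in the combination, and the last 3 of these reversed with a pseudocount of 5.

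The size rule passed 350 genes for 2DG and 319 for aPDL1 in monocytes or macrophages, against 236 genes that moved in opposite directions in the 2DG pairs by the same rule. It passed 170 and 85 in neutrophils against 189, and 127 and 258 in CD8 T cells against 141. Genes that moved in opposite directions in the aPDL1 pairs were not counted. In the 2DG comparison of neutrophils and of CD8 T cells, fewer genes moved alike in both pairs than moved in opposite directions. For 2DG this order turned at 2-fold, with 38 against 28 genes in neutrophils and 21 against 20 in CD8 T cells, and at 10 UMIs, with 768 against 555 and 541 against 473. An effect of 2DG that differs with aPDL1 would raise the opposed count, so it is no baseline without treatment. Medians over all genes were 0.15 and -0.10 in the 2DG pairs and 0.13 and -0.11 in the aPDL1 pairs of monocytes or macrophages, and TMM factors brought them to 0.02, 0.00, 0.00 and -0.01. In neutrophils they were 0.30, 0.16, 0.21 and 0.14, and in CD8 T cells -0.05, -0.08, -0.05 and -0.08, in the same order. The list medians and ratios above are to be read relative to these values.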

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

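The tests of cell filter or depth and of dilution were chosen only after results were seen. All values here come from single libraries, and none of the differences between pairs listed here was tested.

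Several class shares went one way against ctrl and the other way in the pair without ctrl. With 2DG, regulatory T cells differed by 6.13 points alone and -0.936 points on top of aPDL1, cDC1 by 0.423 and -0.522, and all T cells by 35.3 and -1.85, none of which was tested. With aPDL1, CD8 T cells differed by 17.9 points alone and -1.81 on top of 2DG, CD4 T cells by 3.43 and -1.82, regulatory T cells by 2.89 and -4.18, and this was not tested either. In the same pairs all T cells differed by 29.9 and -7.25 points, T and NK cells by 33.5 and -6.27, fibroblastic stroma by 0.144 and -0.184, and monocytes or macrophages by -4.65 and 5.79, also untested. Of these, the CD8 T sign change is absent with cells thinned to 1000 UMIs and gated on marker genes (1.95 points on top of 2DG), and the monocyte or macrophage one is absent with cluster 3 unnamed (12.3 points against ctrl). Fibroblastic stroma is cluster 28 alone, which the versions of the naming rule with 10 CPM left unnamed. An epithelial or tumour marker was then among its leading genes, with no marker of its own class. Its score was 0.814 for fibroblastic stroma and 0.738 for epithelial or tumour cells, so its name is in doubt.

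Gene lists did the same. In the 2DG pairs, immediate early genes had medians of -0.16 and 0.46 in monocytes or macrophages and -0.42 and 0.33 in neutrophils, and these differences were not tested. Sterol synthesis genes had 0.60 and -0.49 in monocytes or macrophages and 0.35 and -0.63 in CD8 T cells, and type I interferon response genes -0.27 and 0.17 in CD8 T cells, likewise untested. In the aPDL1 pairs, monocytes or macrophages had immediate early medians of -0.18 and 0.60 and sterol synthesis medians of 0.61 and -0.35, which were not tested. Unfolded protein response genes had -0.45 and 0.65 in neutrophils, and MHC class II genes 0.59 and -0.43 in CD8 T cells, which were not tested.

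The first pattern weighed was the low share of T and NK cells in ctrl. If the cell filter or depth had made it, the percent of unfiltered barcodes with a Cd3 UMI at 1000 UMIs would have reached at least 0.5 of the lowest other library, but the ratio was 0.196 (0.176 to 0.219), which argues against it. If neutrophils had only diluted the T and NK cells, their share of the remaining cells would have reached at least 0.8 of the lowest other library, but the ratio was 0.248 (0.223 to 0.276), which argues against it too. With 1 ctrl library, another animal, dissection or enrichment of cells could have made the pattern, and so could the treatments. This stays open.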

How the results depend on the processing

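Leaving clusters 3, 6 or 8 unnamed and using the pair without ctrl alone were chosen after results were seen. No paired analysis was possible because there was 1 library per group and the labels name no animal shared by libraries. Of the class share values, 393 kept their label, 41 moved and 6 reversed. Of the gene ratios, 4621 kept it, 498 moved and 42 reversed, and of the list medians 2928, 590 and 10. Where a value moved, the cause was not tested unless a setting names it.

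With at least 1000 genes and at most 5% mitochondrial UMIs, the Neutrophil share, 2DG minus ctrl, was -29.8 points and the Monocyte or macrophage share -13.1. Ctla4 in Neutrophil, aPDL1 over ctrl, was -0.10.

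With 2 times the expected doublet rate removed, the Neutrophil share was -33.5 points for 2DG minus ctrl and -34.5 for aPDL1 minus ctrl. The Monocyte or macrophage share was -8.88 for 2DG minus ctrl and 4.12 for 2DG_aPDL1 minus 2DG, and the T and NK share 34.8 for aPDL1 minus ctrl. In Monocyte or macrophage, Prg4 was -3.26 for 2DG_aPDL1 over aPDL1 and -4.27 over 2DG, Tgfb2 -1.24, Alox15 -8.09 and Cd5l -3.07 over 2DG. For the combination against the nearest library, Vmn2r26 was -2.38, Timd4 -4.72 and Ltbp1 -1.83. In Neutrophil, Hist1h2ap was -0.0139 for 2DG over ctrl and -0.0683 for 2DG_aPDL1 over aPDL1. Hist1h1b was -0.0683 for 2DG_aPDL1 over aPDL1, -1.53 for aPDL1 over ctrl and -2.48 for 2DG_aPDL1 over 2DG, and Ccr9 was -0.33 for the combination. The Cell cycle median in Neutrophil, aPDL1 over ctrl, was -0.12, and the Sterol synthesis median, 2DG_aPDL1 over 2DG, was 0.0699.

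With no doublet removal, Ifng in Monocyte or macrophage, 2DG_aPDL1 over aPDL1, was 0.28, and Lyve1 in the combination was 1.65. The Cell cycle median in Monocyte or macrophage, 2DG over ctrl, was 0.0325, and the T cell activation median was 0.39. In Neutrophil, H2-Aa was -0.0824 for aPDL1 over ctrl and -0.12 for 2DG_aPDL1 over 2DG, and the Ribosomal proteins median was -0.12 for 2DG_aPDL1 over 2DG. In CD8 T, Klra7 was -0.39 for 2DG over ctrl.

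At Leiden resolution 0.5, the Monocyte or macrophage share was -14.8 points for 2DG minus ctrl and -8.02 for aPDL1 minus ctrl. In CD8 T, Klra7 was -0.25 for 2DG over ctrl, Plcb4 1.27 for aPDL1 over ctrl, and Tcf7 -0.77 for 2DG over ctrl and -0.95 for aPDL1 over ctrl. Nckap5 was 1.77 in the combination, and the Naive and homing median, aPDL1 over ctrl, was -0.65.

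At Leiden resolution 2, the Monocyte or macrophage share was -9.31 points for 2DG minus ctrl and -3.12 for aPDL1 minus ctrl, and the T cell activation median there was 0.0102 for 2DG over ctrl. In CD8 T, Klra7 was -0.28, Plcb4 1.01, Tcf7 -0.89 and -1.04, and in the combination Gzme was 3.07 and Nckap5 1.71. The Glycolysis median in CD8 T, 2DG over ctrl, was 0.10, and the Naive and homing median, aPDL1 over ctrl, was -0.70.

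With cluster 3 unnamed, the Monocyte or macrophage share was 8.26 points for 2DG minus ctrl, 1.93 for 2DG_aPDL1 minus aPDL1 and 12.3 for aPDL1 minus ctrl. With cluster 8 unnamed it was -15.7 for 2DG minus ctrl and -9.59 for aPDL1 minus ctrl. With clusters 3 and 6 unnamed, the first naming rule, it was again 8.26, 1.93 and 12.3, and the Neutrophil share was -27.8 for 2DG minus ctrl, -27.5 for aPDL1 minus ctrl and 0.0318 for 2DG_aPDL1 minus 2DG. In Neutrophil, Gm40578 was then -0.51 and -0.45 in the 2DG pairs, Hsph1 was 0.0407 for 2DG_aPDL1 over aPDL1, and Ppp1r16b 0.27 for 2DG_aPDL1 over 2DG. Cd80 was -0.43 and Txnip -0.62 for 2DG over ctrl, Havcr2 was -1.67 for 2DG over ctrl and -0.65 for aPDL1 over ctrl, and the Heat shock median, 2DG_aPDL1 over aPDL1, was 0.0407.

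With cells thinned to 1000 UMIs and gated on marker genes, the CD8 T share, 2DG_aPDL1 minus 2DG, was 1.95 points. With a pseudocount of 5 UMIs, Sptb, Ggt1 and Sdc3 in Neutrophil, combination, were 0.0167, 0.24 and 0.34.

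Of the counts of genes beyond the size rule, 72 kept their label and 18 did not. The 72 likewise include settings that left a class unchanged. In Monocyte or macrophage at least 2-fold left 75 genes for 2DG and 65 for aPDL1 against 44 in opposite directions, at least 10 UMIs gave 752 and 710 against 642, and the pair that does not hold the ctrl library alone gave 1401 and 1324. In Neutrophil these were 38 and 16 against 28, 768 and 517 against 555, and 715 and 658. In CD8 T they were 21 and 51 against 20, 541 and 712 against 473, and 1007 and 1086.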

Other observations

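Beyond the main classes, single genes differed in NK, CD4 T and B cells. These classes held 37, 125 and 136 ctrl cells, under the 200 set for main classes, and B cells held 131 with 2DG. The genes were not chosen by the size rule and no interval is given. Of the ctrl B cells, 19.9% lay in cluster 24, of which 96.4% came from ctrl. NK cells had Gzmb at 2320 CPM in ctrl, 2378 with 2DG, 2168 with aPDL1 and 3237 in the combination. CD4 T cells had Ctla4 at 768, 601, 722 and 1272 CPM, and Ifng, which encodes interferon gamma, at 217, 455, 478 and 590 CPM. B cells had Cd69, an early activation gene, at 307, 406, 434 and 643 CPM.

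The libraries held few transcripts of lymph node stroma, with 1, 0, 3 and 1 UMIs of the chemokine gene Ccl19 and 1, 1, 2 and 1 of Glycam1, a gene of high endothelial venules. With so few of these and with many myeloid cells, the tissue named by the label was not established from the data, and the class shares describe the cells as labelled. The epithelial keratin gene Krt18 was at 0.602 CPM in ctrl, 15.4 with 2DG, 1.91 with aPDL1 and 5.26 in the combination. Mcpt2, a mast cell protease gene, had 334 UMIs in ctrl monocytes or macrophages and 0 in the other 3 libraries, so ctrl was at least 63.8-fold higher than 2DG.

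Of the tests that follow, cluster mix and free RNA for the interferon gamma genes were written before their results, and handling for the heat shock genes was chosen after results were seen.

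Lower interferon gamma response genes in ctrl monocytes or macrophages could come from a different mix of clusters or from free RNA. The median within clusters was taken over 5 clusters with at least 100 cells in every library. It was 0.609 of the class median in one pair with ctrl and 0.640 in the other. Clusters 3 and 2, with 40.4% and 23.2% of the class in ctrl, fell short of that number and were left out. Cluster 21, with 32.7% of the class in the combination, was left out as well, so those cells are not covered. The bound written before against a cluster mix, 0.5, was met, but single clusters ranged from 0.215 to 0.817, and after these values were seen the mix was left open. In the pairs without ctrl, the middle cluster had 0.14 against 0.45 for the class with 2DG, and 0.35 against 0.43 with aPDL1, so the mix stays open there too. For free RNA the bound of 0.5 was also met, as the median in lymphocytes was at most 0.145 of the class median. That test cannot decide on RNA leaking from lymphocytes, which would leave their own values unchanged. Cytotoxic and effector genes had medians in monocytes or macrophages of 1.28 (2DG) and 1.17 (aPDL1) over ctrl. In the pairs without ctrl these medians were -0.28 and -0.13. Free RNA therefore stays open as well.

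Hspa1a and Hspa1b were lowest in the combination, and highest in ctrl, in all 18 class and gene pairs of 9 classes. In CD4 T cells Hspa1b was at 561, 166, 63.1 and 16.7 CPM. A pattern shared by all 9 classes could come from handling, and the 18 pairs are consistent with that. The levels differed among all 4 libraries, so handling of the combination alone would not give the whole pattern, and a treatment effect was not separated from it.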
